A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

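Gene expression was measured in 4 strains of the budding yeast Saccharomyces cerevisiae, with 1 array per strain. The strains were a wild type (W303-1A, a laboratory haploid of mating type a), a ubp10 null, a sir4 null and a ubp10 sir4 double null. Total RNA of exponentially growing cells was hybridised to Affymetrix Yeast Genome S98 arrays, per the labels. Each strain was its own group, so no result has a replicate, a standard error or a p-value, and the number of arrays limits the precision.

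Per the labels, the authors computed the deposited intensity of each probe set with the MAS 4.0 software, as the average difference between perfect-match and mismatch probes. This intensity is linear and can be negative; between 7.4% and 9.4% of the values on an array were below 0. Whether a global scaling was applied is not given in the sources used here. The mean of the values between the 2nd and the 98th percentile was 100.0 on each of the 4 arrays, so the values were used as deposited, by a rule that asked for trimmed means within 5% of each other.

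Each array held 9335 probe sets, of which 60 were controls and 9275 were not. Gene names came from the platform annotation, updated through gene identifiers to the current RefSeq table of the species. Of the 9275 probe sets, 6504 had 1 gene symbol and all 6504 matched that table, 328 had several symbols and 2443 were not listed. Probe sets with several symbols named no gene, except in the accounts of the silent mating cassettes and of shared family probe sets. The 6504 probe sets gave 5656 genes, 315 of them with more than 1 probe set. No genome sequence was used, so no coordinates are given.

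The noise SD was taken from the negative values, mirrored about 0, and was 2.22 intensity units. Values below a floor of 3 noise SDs, 6.67 units, were raised to it. A gene's value was the mean log2 of its floored probe sets. A gene was called higher or lower when its brighter value was at least 2 times the floor (13.3 units) and the ratio was at least 2. A ratio against an array at the floor is a lower bound and is written as at least N-fold. Where the median log2 ratio of genes above the floor on both arrays moved by more than 0.1, folds and log2 ratios, lower bounds included, are given relative to that median, while the calls use the values as deposited.

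The 5 comparisons were each mutant against wild type, and the double null against each single null. An additive fit over the 4 arrays was not used, because it would treat the interaction of the 2 deletions as error. Gene lists were fixed before the data were examined; there were 40, of which 36 had the minimum of 4 measured members. For each, the median log2 ratio was placed among those of 10000 random lists of the same size, matched on mean expression in 10 bins. A list stood apart when its percentile was under 2.5 or over 97.5, which describes these arrays and is not a test of the strains. Subtelomeric genes were the 10 outermost open reading frames in the gene table on each of the 32 chromosome arms, by the number in the systematic name. Open reading frames with only shared or unlisted probe sets were left out, so genes further in could take their place.

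Named genes followed a rule fixed before the data were examined. It took the targeted genes, then the 10 largest rises and falls measured above the floor on both arrays, and the 5 brightest called genes per direction whose other value was at the floor. It added up to 4 members of each list that stood apart or held a call, and the mating-type genes. For the double null against each single null it took 6 and 3 in place of 10 and 5.

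Correlations were computed across genes, which are not independent replicates. For comparisons that share the wild-type array, 100 simulations of unchanged groups gave the correlation and covariance due to the shared array alone. The calling rule was tested on simulated data for ubp10 null against wild type, over 5656 genes with 50 genes changed at each fold. The changed genes were drawn from those with a mean of at least 4 times the floor, so recovery among dimmer genes was not tested. With the whole observed spread taken as noise, 50.0% of the 2-fold changes, 86.0% of the 3-fold, 90.0% of the 4-fold and 98.0% of the 8-fold changes were recovered. In that setting 13.4% of the unchanged genes were called, against 0.5% with the noise reduced by a factor of 2.

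Alternatives were quantile normalization, cyclic loess, centring of the median ratio, scaling to a common trimmed mean, a floor halved or doubled, ratios of 1.5 and 3, other brightness rules, other subtelomeric sets, unmatched random lists, and plain probe sets alone. A ratio taken against the median ratio, and quantile normalization without the array labelled sir4 null, were chosen after seeing the data. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1 for the quantile and loess settings. Leaving out replicates was not applicable with 1 array per strain.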

Results

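The expression of 5656 genes was compared between 4 yeast strains that carried or lacked UBP10 and SIR4. UBP10 encodes a ubiquitin-specific protease that removes ubiquitin from histone H2B, and SIR4 a component of the silencing complex that acts at telomeres and at the silent mating cassettes. Each strain was represented by 1 array, so no difference below has a replicate check. The arrays had 69.4% (wild type), 73.7% (ubp10 null), 71.7% (sir4 null) and 73.1% (double null) of non-control probe sets above the floor.

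The targeted genes were examined first. UBP10 had 247.9 intensity units in the wild type and 269.2 on the array labelled sir4 null. It lay at the floor on the ubp10 null and double null arrays, at least 37.2-fold below wild type on the values as deposited. SIR4 was dim throughout, with 10.8 units in the wild type, 20.7 on the array labelled sir4 null and 15.5 on the double null array, and was at the floor on the ubp10 null array. The SIR4 probe set was thus not lower than wild type on the arrays labelled as lacking SIR4. It was called higher in the double null than in the ubp10 null, at least 2.3-fold as deposited and at least 1.64-fold relative to the median ratio. Its wild-type value was near the floor and under the brightness minimum for a call, so a loss of SIR4 could hardly show. These values therefore cannot decide for or against the sir4 labels. Whether the probe set lies in the deleted part is not given in the sources used here. The array of the sir4 single null is called the array labelled sir4 null throughout, and the directions below that rest on the sir4 genotype rest on the labels.

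RNA controls set the array labelled sir4 null apart. The probe set for the 5′ end of ACT1, the actin gene, read 16.1 units there against 1399.6 for the 3′ end, an 86.9-fold difference, while the other 3 arrays had 1.1- to 1.5-fold. For SPT15, which encodes the TATA-binding protein, the 3′ end was 18.7-fold brighter than the 5′ end on that array and 1.5- to 2.1-fold brighter on the others. Among genes with more than 1 probe set, those probe sets differed by over 4-fold in their ratio to wild type in 117 of 219 genes on that array, in 35 of 227 in the ubp10 null and in 20 of 226 on the double null array. In the double null against the ubp10 null it was 80 of 238, so such differences were not limited to the array labelled sir4 null.

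**Figure D1:**
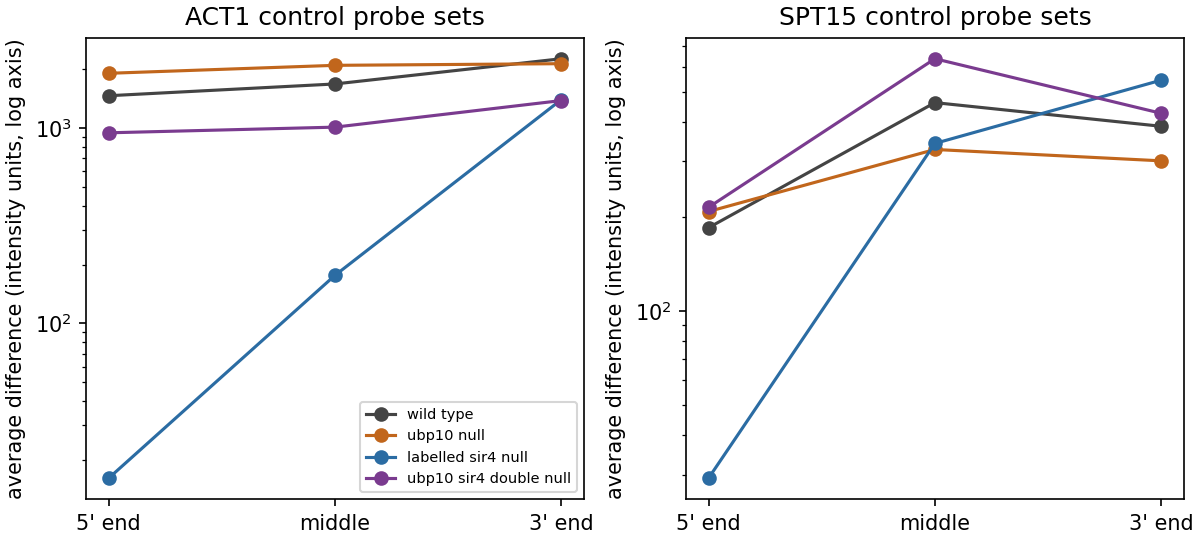
Average difference (intensity units, log axis) of the control probe sets for the 5′ end, middle and 3′ end of ACT1 (left) and SPT15 (right), 1 line per array. The array labelled sir4 null fell to 16.1 units at the 5′ end of ACT1, where the other 3 arrays stayed between 945.5 and 1907.3.

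Removal of UBP10 alone was accompanied by higher levels of stress-responsive genes. Of 27 general stress genes, 19 were higher, 0 were lower and 8 were not called, with a list median log2 ratio of 2.05 at the 100th percentile of matched random lists. SPI1, a cell wall protein induced by stress, was 31.8-fold higher, and HXK1, a hexokinase, at least 24.6-fold. GAD1, glutamate decarboxylase, was at least 19.8-fold higher and GPH1, glycogen phosphorylase, at least 14.0-fold. Of 22 heat shock and chaperone genes 11 were higher and 0 lower, with a median of 1.01, also at the 100th percentile. HSP30, a plasma membrane heat shock protein, rose from the floor to 1535.5 units, at least 230.2-fold, SSA4, an inducible Hsp70, was 30.5-fold higher, HSP42 21.9-fold and HSP26 at least 23.2-fold.

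The largest rise measured on both arrays was that of ARO10, a decarboxylase of aromatic amino acid breakdown, at 78.8-fold, and ARO9, the aminotransferase of the same pathway, was 34.7-fold higher. RTC3 was 39.9-fold higher, STP4 25.5-fold, TPO4 23.3-fold, CIP1 17.2-fold and BTN2 16.0-fold. RGI1, EGO4, ROQ1 and MGA1 rose from the floor by at least 66.7-, 59.0-, 40.9- and 26-fold. Among other lists above matched genes, 5 of 10 seripauperins (PAU genes) were higher and 0 lower, with a median of 1.00, PAU10 leading at 2.9-fold; their near-identical copies can share signal. Cell wall genes had 4 higher and 2 lower of 20, with PIR3 3.1-fold and PST1 2.9-fold higher, and iron genes 3 higher and 1 lower of 24, with the heme oxygenase HMX1 6.8-fold higher. The 6 maltose genes stood apart with a median of 0.57 and 0 calls. With the floor doubled, the iron, maltose and phosphate lists no longer stood apart (percentiles 92.58, 48.49 and 12.44), nor did the cell wall list against unmatched random lists (96.97).

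Amino acid, phosphate and ergosterol genes lay lower in the ubp10 null. Of 44 amino acid biosynthesis genes 12 were lower and 1 was higher, with a median log2 ratio of -0.68 at percentile 0.00, including TRP4 (3.3-fold), ARG3 (3.2-fold), TRP2 (3.1-fold) and LYS2 (2.8-fold). Phosphate genes had 5 lower and 1 higher of 14, with the phosphate transporter PHO84 6.2-fold and the polyphosphate genes VTC3 and VTC1 3.4- and 2.8-fold lower, whereas PHM8 was at least 14.1-fold higher. Of 22 ergosterol genes 3 were lower, among them CYB5 (2.6-fold), ERG24 (2.4-fold) and ERG4 (2.2-fold). Falls reached 6.2-fold for the sulfite pump SSU1, 6.1-fold for YGR079W, 5.8-fold for BFR2 and 4.7-fold for SNZ1, a gene of vitamin B6 synthesis. Cytosolic ribosomal proteins stayed level, with a median of -0.04 and 78 of 81 not called.

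In total 534 genes were higher and 476 lower in the ubp10 null than in the wild type, by size alone. The 10 lists that stood apart, of 36, compare with 1.8 for random lists. Genes of a real list can move together, so this is not a measure of chance. The a-specific genes were among them, with a median of -0.89; AGA2 and BAR1 were each 2.0-fold lower and the other 5 of 7 were not called. The haploid-specific list did not stand apart (percentile 17.99), with GPA1 3.3-fold and HO 2.8-fold lower, and STE3, an alpha-specific gene, was 2.4-fold higher.

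Removal of SIR4 alone was read from the array labelled sir4 null. Genes above the floor on both arrays had a median log2 ratio of 0.49, and the values that follow are relative to it. Among genes above the floor on both arrays, ARO10 and ARO9 were the most raised, 20.3- and 18.5-fold, followed by INO1, inositol phosphate synthase, at 9.8-fold, SDH6 and SPC1 each at 7.8-fold, COB at 7.2-fold and YGP1 at 6.9-fold. Of 14 phosphate genes 9 were higher and 1 was lower, 0.87 above the matched lists at the 100th percentile, with SPL2 5.1-fold, PHM8 at least 4.1-fold and PHO84 2.8-fold higher. Genes at the floor in the wild type included COX26, COX3, AAC1 and CYB2, at least 19.5-, 14.7-, 12.7- and 11.6-fold higher. The respiratory chain list, with 1 higher and 1 lower of 35, and the mitochondrial DNA-encoded list, with 3 higher and 1 lower of 8, did not stand apart (percentiles 95.32 and 48.64), although with plain probe sets alone the latter lay 1.35 log2 units above matched lists.

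Lists below their matched genes on that array included glycolysis, with 8 lower and 1 higher of 16 (-0.89 log2 units from matched lists, percentile 0.00), and cytosolic ribosomal proteins, with 18 lower of 81. TDH3 was 3.3-fold and CDC19, pyruvate kinase, 3.1-fold lower (2.3- and 2.2-fold as deposited). The 98th percentile of intensity was 1033 units there against 1484 in the wild type, and its part in the fall of bright lists was not tested. RPL7B was 48.3-fold, RPS0A 20-fold, RPS0B 15.5-fold and RPL7A 15.2-fold lower. The probe sets of RPS0A did not move alike there: 1 read 11.0 units against 1238.0 in the wild type, and another 885.3 against 1580.5. The medians of purine genes (6 lower, 1 higher of 17), cell wall genes (4 lower, 1 higher of 20), iron genes (3 lower, 4 higher of 24) and the COS family (1 lower, 0 higher of 8) also lay below matched genes. HMX1 and FRE1, in the iron list, were 4.9- and 3.6-fold higher; IMD4, GCV1, HSP150, MRS4 and COS7 were 10.9-, 9.1-, 6.3-, 7.7- and at least 5.1-fold lower. The COS list did not stand apart under cyclic loess (percentile 3.45), with the median ratio centred (4.55) or with plain probe sets alone (16.82), nor the iron list against unmatched random lists (2.56). YNL190W fell 73.3-fold and the RNA helicase DED1 20.9-fold, each on a single probe set.

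Heat shock genes did not stand apart (percentile 52.43) but did so under quantile normalization and cyclic loess (98.47 and 98.96). Mating genes stayed expressed on the array labelled sir4 null. MFA2 and MFA1, the a-factor precursors, read 761.0 and 404.6 units, STE2, the alpha-factor receptor, 174.4, and 0 of 7 a-specific genes were called on the values as deposited, although their median lay at -0.96 log2 units from matched genes (percentile 0.32). Relative to the median ratio, MFA1, MFA2 and BAR1 were each 2.1-fold lower. Of 12 haploid-specific genes 2 were higher (HO and GPA1, each 2.1-fold) and 1 was lower (FUS3, 2.9-fold), and the list did not stand apart (percentile 37.17). Counts depended on scaling: 1120 genes were higher and 253 lower as deposited, 359 and 510 with the median ratio centred, 416 and 359 under quantile normalization, and 243 and 492 under cyclic loess. The 5′ signal loss described above applies to all the values in this comparison.

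Removal of both genes was accompanied by far lower levels of mating-type transcripts. Against wild type, the median log2 ratio above the floor was 0.54, and values are relative to it. Of 7 a-specific genes 6 were lower and 0 higher: MFA2 fell 110.1-fold, to 14.8 units, MFA1 47.7-fold, BAR1, the alpha-factor protease, 30.0-fold, STE2 at least 50.5-fold and AGA2 at least 23.8-fold. Of 12 haploid-specific genes 10 were lower and 0 higher, with FAR1 at least 26-fold, the mating-switch endonuclease HO at least 17.0-fold, RME1, a repressor of meiosis, 17.0-fold and the G protein subunit GPA1 11.6-fold. The lists lay at -4.88 and -3.03 log2 units from matched genes, both at percentile 0.00. Of 4 alpha-specific genes only STE3 was called, 2.4-fold higher, and MF(ALPHA)1, with 8.4 units, stayed near the floor.

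**Figure D2:**
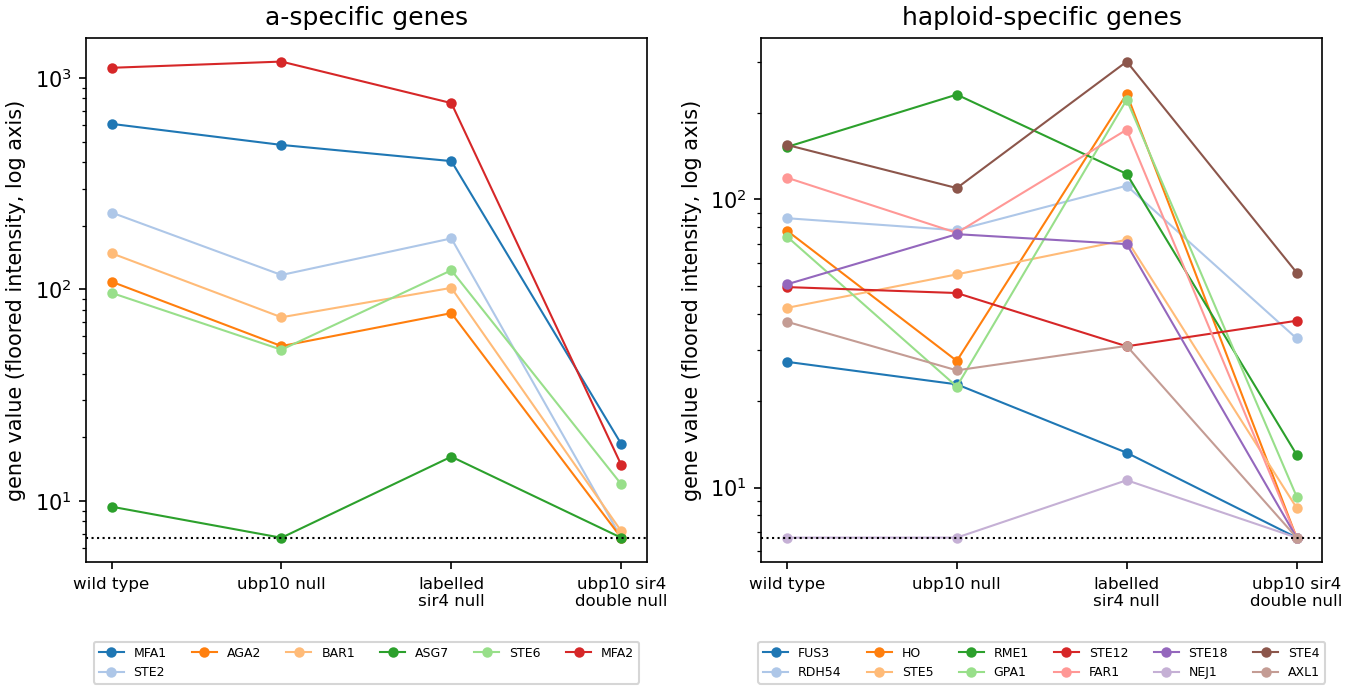
Values (floored intensity, log axis) of 7 a-specific genes (left) and 12 haploid-specific genes (right) on the 4 arrays, 1 line per gene, with the floor of 6.67 units dotted. MFA2 read 1117.4, 1195.7, 761.0 and 14.8 units in the wild type, the ubp10 null, the array labelled sir4 null and the double null.

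The silent mating cassettes hold copies of the mating-type genes that SIR-dependent silencing keeps off. A probe set shared by the alpha1 copies read 17.3 units in the wild type, 14.8 in the ubp10 null, 57.2 on the array labelled sir4 null and 93.1 in the double null. Another alpha1 probe set stayed under the floor on all 4 arrays. The 2 probe sets shared by the copies of alpha2 did not move alike: in the same order, 1 read 49.2, 65.4, 143.0 and 143.8 units and the other 24.6, 82.8, 30.2 and 71.3. Of 3 probe sets for HMRA1, the brightest read 88.1, 279.3, 252.4 and 216.6 units and was highest in the ubp10 null. The other 2 were under the floor in the wild type and the ubp10 null and read 15.0 and 20.2 units on the array labelled sir4 null and 14.2 and 14.7 in the double null. The alpha1 and alpha2 probe sets are listed for several copies, so the locus their signal came from is not resolved. The HMRA1 probe sets are listed for that gene alone, but the active mating-type locus of an a strain holds a copy of it, so their locus is not resolved either.

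Stress and iron genes were also higher in the double null than in the wild type. Of 27 general stress genes 19 were higher and 1 lower, 0.88 above matched lists at the 100th percentile, including HXK1 (at least 12.5-fold), HSP12 (6.1-fold), SOL4 (3.8-fold) and TSL1 (3.6-fold). Of 22 heat shock genes 7 were higher and 0 lower, a standing lost with the floor doubled (percentile 90.54), with plain probe sets alone (95.87) and against unmatched random lists (60.38). Iron genes had 9 higher and 0 lower of 24 (HMX1 4.7-fold, FRE1 2.8-fold, CCC2, a copper transporter, 2.6-fold), and respiratory chain genes 5 higher and 0 lower of 35 (CYC7 3.0-fold, NDI1 2.3-fold), the latter not apart from unmatched random lists (percentile 96.14). Among all genes 18.6% were called higher in this comparison, a share that the respiratory chain count did not exceed. ARO10 and ARO9 were 29.8- and 22.4-fold higher, SDH6 8.9-fold, HPF1 6.8-fold and CYB2 at least 13.7-fold. Lower lists included amino acid biosynthesis (3 of 44 lower, ARG1 3.5-fold), glycolysis (4 of 16 lower, 1 higher, PDC1 3.4-fold) and cytosolic ribosomal proteins (14 of 81 lower, RPL22A 3.9-fold); SNO1 and SNZ1 fell 28-fold and 12-fold. Counts were 1051 higher and 117 lower as deposited, 293 and 318 with the median ratio centred, 276 and 172 under quantile normalization and 245 and 212 under cyclic loess. The standing of the glycolysis list was lost under quantile normalization and cyclic loess (percentiles 3.97 and 5.96). The 98th percentile of intensity was 991 units in the double null against 1484 in the wild type. Its part in the fall of the bright ribosomal protein and glycolysis genes was not tested, and RPL22A was 2.7-fold lower as deposited.

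Removal of SIR4 where UBP10 was already gone also came with lower mating genes, read from the double null against the ubp10 null and relative to a median of 0.50. The a-specific genes had 6 lower and 0 higher of 7, with MFA2 114.2-fold and MFA1 36.8-fold lower. Haploid-specific genes had 9 lower and 0 higher of 12, RME1 by 25.1-fold. Stress genes lay below the ubp10 null: 9 of 27 general stress genes were lower and 2 higher, -0.92 log2 units from matched lists, with SPI1 15.6-fold and GAD1 9.7-fold lower, and 8 of 22 heat shock genes were lower and 1 higher. HSP30 fell 168.3-fold, from 1535.5 to 12.9 units, SSA4 29.7-fold and BTN2 10.9-fold. YRO2, RTC3 and CIP1 fell 33.4-, 31.8- and 31.3-fold, and ROQ1 and MGA1 at least 57.8- and 36.8-fold.

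Higher in that comparison were 8 of 14 phosphate genes, with 1 lower (PHO84 4.9-fold higher, VTC3 3.3-fold higher, PHM8 7.2-fold lower), and 6 of 22 ergosterol genes, with 1 lower (CYB5 3.6-fold, ERG8 2.1-fold). Respiratory chain genes had 9 higher of 35. Among all genes 28.3% were called higher in this comparison, a share that the ergosterol and respiratory chain counts did not exceed. SPG5, CYB2, CAK1 and ERG29 rose 14.8-, 12.2-, 8.8- and 7.5-fold. Ribosomal proteins (20 of 81 lower), glycolysis (7 of 16 lower) and cell wall genes (6 of 20 lower, 1 higher) lay under matched genes, and the seripauperins (0 lower, 1 higher of 10) at -0.86 log2 units from them. The standing of the glycolysis list was lost under quantile normalization and cyclic loess (percentiles 2.71 and 2.55), and that of the phosphate list with the floor doubled (89.92). The 98th percentile of intensity was 991 units in the double null against 1577 in the ubp10 null, and its part in the fall of bright lists was not tested. Against unmatched random lists the ergosterol and respiratory chain lists did not stand apart (84.23 and 80.58). Counts were 1598 higher and 354 lower as deposited, 764 and 736 with the median ratio centred, 1011 and 508 under quantile normalization and 771 and 617 under cyclic loess.

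Removal of UBP10 where SIR4 was already gone, read from the double null against the array labelled sir4 null, gave 449 genes higher and 176 lower. Mating genes were lower here too, in 7 of 7 a-specific and 9 of 12 haploid-specific genes: MFA2 fell 51.4-fold, GPA1 23.8-fold, MFA1 21.8-fold and HO at least 34.8-fold. The pheromone response list, with 4 of 15 lower, also lay below matched genes (SST2, a regulator of G protein signalling, 3.5-fold; PRM5 2.6-fold). Phosphate genes had 5 lower of 14 (SPL2 4.1-fold, PHO84 3.4-fold), and genes encoded in mitochondrial DNA 5 lower of 8 (COX2 7.5-fold, COX3 6.3-fold, COB 3.7-fold). Higher lists were general stress (9 higher and 1 lower of 27; HXK1 7.6-fold, HSP12 3.3-fold), iron (10 higher and 1 lower of 24; MRS4 9.5-fold), purine (7 of 17; ADE17 14.5-fold, GCV1 5.7-fold), respiratory chain (7 of 35; RIP1 4.1-fold), maltose (2 of 6; MAL33 3.0-fold), COS (3 of 8; COS7 at least 5.2-fold) and cell wall genes (2 of 20; HSP150 2.8-fold), beside the marker genes below. With plain probe sets alone the COS and cell wall lists did not stand apart (percentiles 70.75 and 96.81). Some of these members were low on the array labelled sir4 null and not above wild type in the double null. GCV1 read 100.9, 15.6 and 89.6 units in the wild type, on that array and in the double null. HSP150 read 1487.1, 330.6 and 916.3 in the same order. Others ended above the wild type, such as ADE17 (87.6, 28.1 and 408.7) and RIP1 (375.4, 172.0 and 700.3).

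Genes of the auxotrophic marker list differed between these arrays: LEU2 was 10.3-fold, HIS3 3.7-fold and ADE2 3.5-fold higher in the double null. HIS3 and ADE2 were also called higher in the ubp10 null than in the wild type, 2.8- and 2.5-fold, whereas LYS2 of the same list was 2.8-fold lower there. In the wild type, the ubp10 null, the array labelled sir4 null and the double null, HIS3 read 33.5, 93.8, 48.8 and 180.6 units. ADE2 read 27.3, 68.3, 38.1 and 133.7 in the same order. The LEU2 probe sets moved apart on the array labelled sir4 null, with least and most changed log2 ratios to wild type of 0.75 and -4.82. YNL190W (29.0-fold), YME1 (14.3-fold), RPL7B (13.5-fold) and DED1 (12.1-fold) were higher in the double null and were far lower on the array labelled sir4 null than on every other array. Probe sets of a gene differed by over 4-fold in their ratio in 112 of 224 genes in this comparison.

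**Figure D3:**
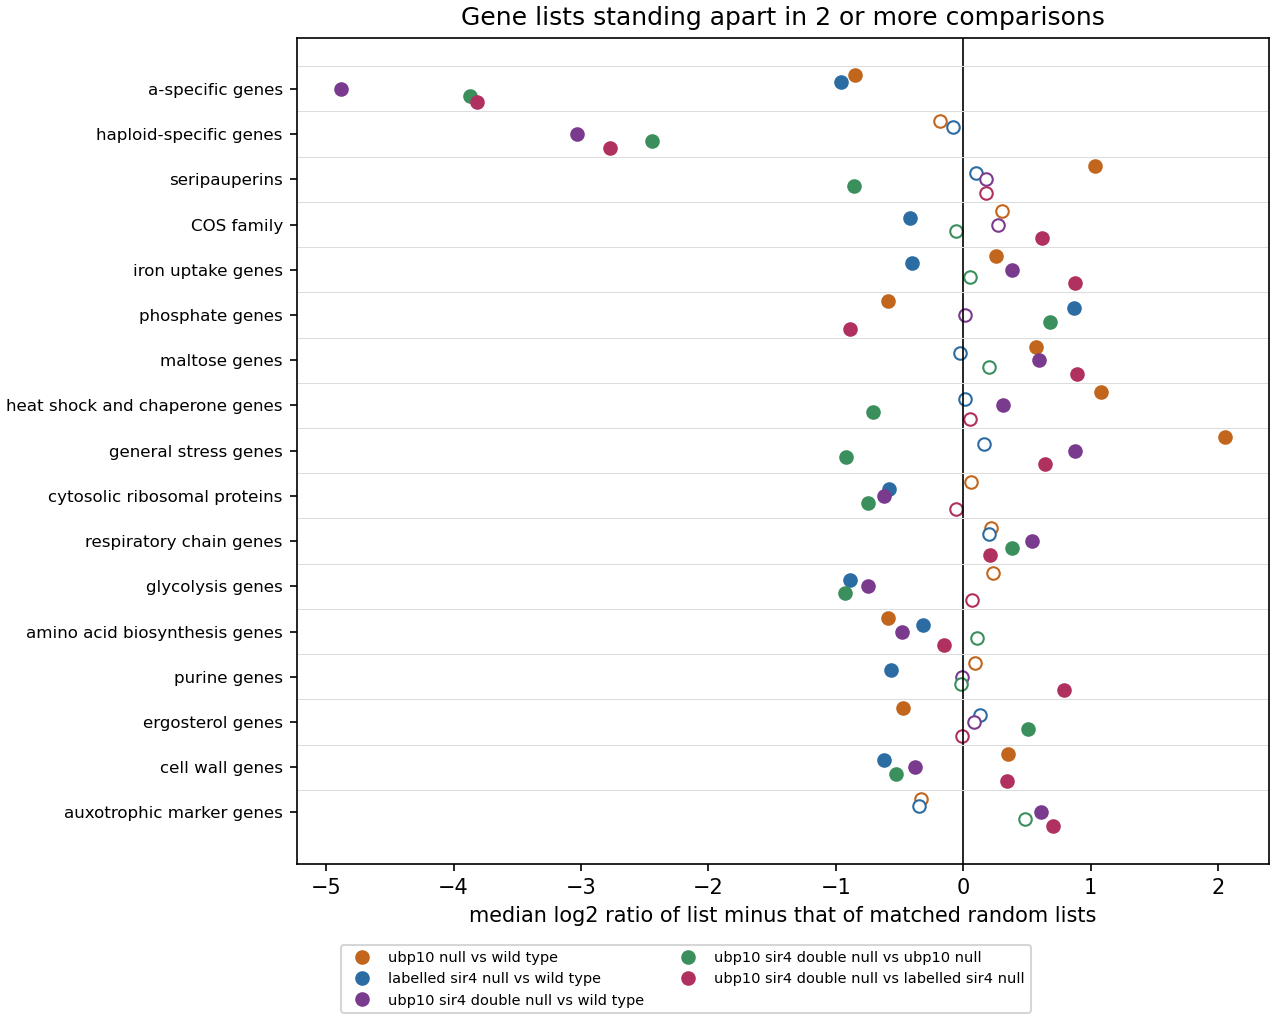
Median log2 ratio of each list minus that of matched random lists, for the 17 lists that stood apart in 2 or more comparisons; filled points stood apart and open points did not. General stress genes lay 2.05 above matched lists in the ubp10 null against wild type, and a-specific genes at -4.88 in the double null against wild type.

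Telomere-proximal genes, where SIR-dependent silencing acts, were compared as a set of 320, drawn from genes with a probe set listed for them alone. In the ubp10 null 27 were higher and 26 lower, against medians of 29 and 21 in matched random sets, and the set's median log2 ratio was 0.00, at percentile 50. On the array labelled sir4 null 47 were higher and 19 lower (random medians 58 and 12), the lower count at percentile 97.6 of the random sets, with a median of 0.18 at percentile 3.4. The double null had 56 higher and 12 lower than wild type (random medians 57 and 5; median 0.39, percentile 40.6), the lower count at percentile 99.4. Against the ubp10 null it had 70 higher and 19 lower (79 and 20; median 0.30, percentile 64.7). Against the array labelled sir4 null it had 34 higher, at percentile 98 of the random sets (94.4 without multigene families), and 11 lower (24 and 10; median 0.00, percentile 49.5). These 3 count percentiles were 99.0, 98.8 and 99.1 for the 5 outermost genes per arm and 78.2, 99.0 and 81.2 for the 20 outermost. Among the 20 outermost, fewer genes were higher than in random sets in the ubp10 null (40 against 59, percentile 0.1) and on the array labelled sir4 null (101 against 122, percentile 1.0). Among the 5 outermost, 28 against 39 were higher in the double null than in the ubp10 null (percentile 1.3). The set median stood apart in 0 of the 5 comparisons. Shared family probe sets, outside this set, were counted as higher and lower in the ubp10 null, labelled sir4 null and double null against wild type. The 24 for Y′ helicases had 3 and 2, 4 and 5, and 0 and 5. The 7 for the COS family had 0 and 0, 2 and 1, and 4 and 0. For seripauperins the 12 had 6 and 0, 3 and 0, and 4 and 0.

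The effect of removing UBP10 was compared with and without SIR4, across 4642 genes above the floor on all arrays and with no array in common. Pearson's r across genes was 0.17 and Spearman's rho 0.19; genes are not independent replicates. Of 534 genes higher in the ubp10 null, 93 were also higher in the double null against the array labelled sir4 null (42 for independent lists), and of 476 lower genes 33 were also lower (15). HMX1 was higher in the ubp10 null, on the array labelled sir4 null and in the double null (335.3, 341.4 and 337.5 units against 49.3 in the wild type). The effect of removing SIR4 with and without UBP10 gave r 0.42 and rho 0.45, with 635 of 1120 higher genes (316 for independent lists) and 68 of 253 lower genes (16) shared. Both of these comparisons carry a median shift (0.49 and 0.50) and added controls that were lower (-0.97 and -2.08), and r was 0.32 under cyclic loess and 0.33 under quantile normalization. The ubp10 and sir4 effects, both against the same wild-type array, gave r 0.01, rho -0.05 and a covariance of 0.009. Against that array, the double null effect gave r 0.19 with the ubp10 effect and r 0.61 with the sir4 effect (covariances 0.103 and 0.332). Simulated unchanged groups that share a control gave r 0.50 and a covariance of 0.259, a figure that counts all spread between the arrays as noise.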

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

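All tests of explanations in this part, and the 4-fold cut that defines the last pattern, were chosen after the result was seen.

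Some genes moved in opposite directions when the same deletion was made in the other background; these differences were not tested, since each strain had 1 array. For removal of UBP10, 19 genes were higher with SIR4 present and lower without it, and 19 lower and then higher. For removal of SIR4, 36 genes were higher with UBP10 present and lower without it, and 24 lower and then higher. More genes kept their direction, 93 higher and 33 lower for UBP10 and 635 and 68 for SIR4. The lists behind these counts were large (for SIR4, 1120 higher and 253 lower with UBP10, 1598 and 354 without). Independent lists would thus also overlap in opposite directions. That number was not computed, so the counts are not read as an excess.

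Probe sets outside the gene table also differed from the wild type. Ribosomal RNA control probe sets read 48.9 and 39.3 units (18S) and 27.6 and 75.0 units (25S) on the ubp10 null array, where the wild type had 11.6 or less. Among 2443 probe sets not listed in the annotation, 8.88% were higher in the ubp10 null than in the wild type, 12.4% on the array labelled sir4 null and 7.65% in the double null, while 2.66%, 5.36% and 10.27% were lower. Among genes 9.4%, 19.8% and 18.6% were higher and 8.4%, 4.5% and 2.1% lower.

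In the double null 6 of 7 a-specific genes and 10 of 12 haploid-specific genes were called lower than in the wild type, against 0 and 1 on the array labelled sir4 null, although both are labelled as lacking SIR4. A culture of alpha cells with silent cassettes is argued against, because haploid-specific genes, which both mating types express, lay at -3.03 log2 units from matched genes in the double null. Alpha cells with open cassettes are not covered by this, since that state lowers haploid-specific genes too. An a/alpha diploid cannot be told apart from a haploid with open cassettes: the haploid-specific list was at percentile 0.0, and both states lower it. A strain with working SIR4 on the array labelled sir4 null also stays open: 4 of 7 probe sets listed for cassette genes lay at least 2-fold above wild type beyond the median shift there, against 2 of 7 in the ubp10 null and 2 of 7 in the double null (another at 1.99-fold), but 3 of the 7 were under the floor in the wild type, so their folds are lower bounds or unmeasured. At 3-fold the order changed, with 0 of 7 on that array, 2 of 7 in the ubp10 null and 1 of 7 in the double null. On the floored values 4 of the 7 were higher on both arrays labelled as lacking SIR4 than on both others, and the loss of SIR-dependent silencing, named by the design, remains a hypothesis that these arrays leave untested.

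Stress and heat shock genes were raised on the ubp10 null array. A culture leaving exponential growth would lower ribosomal protein genes, whose median was at percentile 78.61 of matched lists, so this sign of it was absent. That list alone does not exclude it with 1 culture per strain. Among sugar-use genes, HXT4, HXT6, HXT7 and TDH1 were 5.5-, 4.1-, 3.7- and 12.2-fold higher and HXT2 was 2.3-fold lower. Stress of a single culture cannot be told apart from an effect of the deletion, with 1 culture per strain. In the double null against the array labelled sir4 null, which shares no array with that comparison but rests on the array with the 5′ signal loss, general stress genes were again at percentile 100 and heat shock genes at 73.84. The heat shock list, with 4 higher and 0 lower of 22 genes, did not stand apart there. On the array labelled sir4 null, which keeps UBP10, general stress genes stood apart from matched lists only with the floor halved (percentile 98.45). HSP12, HXK1, TSL1, GLC3, PGM2 and YGP1 were higher than wild type on all 3 mutant arrays, which a low wild-type value alone would also give. The double null also lacks UBP10, yet against the ubp10 null more of its general stress and heat shock genes were lower than higher, as given above. HSP30 fell there from 1535.5 to 12.9 units. Against wild type, general stress genes stayed higher in the double null. An effect of UBP10 on the general stress genes remains a hypothesis that may be worth a replicated test.

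On the array labelled sir4 null, 40 genes lay at least 4-fold lower than on every other array, against 7 to 13 genes for the other arrays. In the other direction the ubp10 null array stood out, with 56 genes at least 4-fold higher than on every other array, against 1 to 5. The low genes did not hinge on the scaling used, since 40 stayed at least 4-fold lower under cyclic loess, 38 under quantile normalization and 36 with the median ratio centred. The median shift of that array against wild type, 0.49 log2 units, was small beside the 4-fold cut. These settings were thus unlikely to remove the pattern. Loss of 5′ signal is consistent with the probe sets: of 10 such genes with more than 1 probe set, 8 had a probe set within 2-fold of wild type beside another at least 4-fold lower. Which end of the transcript those probe sets match is not known here, and a real fall of the 30 genes with a single probe set stays open.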

How the results depend on the processing

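Counts of calls depended on the ratio asked for and, for comparisons across the split between wild type and ubp10 null and the other pair of arrays, on scaling. Counts are given as higher and lower, in the order ubp10 null, labelled sir4 null and double null against wild type, then double null against ubp10 null and against the array labelled sir4 null. At 3-fold they were 215 and 107, 254 and 110, 224 and 42, 642 and 156, 186 and 61. At 1.5-fold they were 1033 and 1056, 2224 and 489, 2362 and 292, 2376 and 666, 869 and 523; fewer or more calls follow from the threshold itself. For the array labelled sir4 null and the double null against wild type, and the double null against the ubp10 null, counts were 359 and 510, 293 and 318, 764 and 736 with the median ratio centred; 243 and 492, 245 and 212, 771 and 617 under cyclic loess; and 416 and 359, 276 and 172, 1011 and 508 under quantile normalization. Against the median ratio, an alternative chosen after seeing the data, they were 341 and 546, 243 and 375, 756 and 749. Quantile normalization without the array labelled sir4 null, also chosen afterwards, gave 272 higher in the double null than in wild type and 1009 higher than in the ubp10 null.

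The median of subtelomeric genes moved with the shift of all genes. Against wild type, the array labelled sir4 null gave 0.00 with the median ratio centred, under cyclic loess and under quantile normalization, 0.02 with the floor doubled, 0.29 with it halved and 0.32 for the 20 outermost genes, and the double null gave 0.00, 0.02, 0.05 and, with the floor doubled, 0.21. The double null against the ubp10 null gave 0.00, 0.00, 0.03, 0.08 with the floor doubled and 0.11 for the 5 outermost genes. Against the array labelled sir4 null it gave 0.01 under cyclic loess and 0.04 with the floor halved. The correlation of the sir4 effect with and without UBP10 was 0.32 under cyclic loess and 0.33 under quantile normalization. The cause of these moves was not tested. Of 191 such values, 130 stayed the same.

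Of 478 list results, 431 kept their side, 46 no longer stood apart, and the hexose transporters on the array labelled sir4 null turned to -0.13 against random lists not matched on expression. Lists that had not stood apart gained standing in 30 of 957 reruns. Heat shock genes on the array labelled sir4 null reached percentile 98.47 under quantile normalization and 98.96 under cyclic loess, and pheromone response genes in the double null against wild type 0.15 and 0.01. Of 3762 named-gene results, 3337 kept their call, 394 lost it, 31 gained it and 0 turned. No paired analysis was possible because each strain had 1 array and the labels share no replicate number. Signal near the floor of 6.67 units limits what dim genes, SIR4 among them, can show.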

Other observations

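Across the 3 mutants, 85 genes were higher than wild type in all 3 and 8 were lower in all 3, against the same wild-type array, so a low or high wild-type value alone would give such a set. ARO9 read 21.5 units in the wild type and 745.6, 559.9 and 702.8 in the ubp10 null, on the array labelled sir4 null and in the double null, and ARO10 13.3 against 1048.2, 380.9 and 577.8. The 8 lower genes, chosen after their values were seen, were SEO1, PHO3, TMT1, IRC7, YHK8, SNO1, SNZ1 and SSU1. SNO1 and SNZ1, which act together in vitamin B6 synthesis, read 365.1 and 648.9 units in the wild type and 19.0 and 78.6 in the double null.

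Hexose transporters showed mixed behaviour in the ubp10 null, with HXT4 5.5-fold, HXT6 4.1-fold and HXT7 3.7-fold higher and HXT2 2.3-fold lower. The glycolytic isozyme TDH1 was 12.2-fold higher there, while the other 15 of 16 glycolysis genes were not called. In the cyclin list, SIC1, an inhibitor of a cyclin-dependent kinase, and the cyclins CLN3 and PCL2 were 2.6-, 2.4- and 2.3-fold higher, while the other 13 of 16 were not called and the list did not stand apart (percentile 28.92). In the sulfur amino acid list, MET2 was 4.9-fold higher and the sulfate permease SUL1 3.3-fold lower.

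Added hybridisation controls, 9 probe sets, differed in level between arrays by a median log2 ratio of 0.25 for the ubp10 null against wild type, -0.97 for the array labelled sir4 null and -1.75 for the double null. The median intensity was 24.0, 26.2, 34.1 and 38.0 units and the 98th percentile 1484, 1577, 1033 and 991 units, in the order wild type, ubp10 null, array labelled sir4 null and double null. Across genes, the double null correlated more closely with the wild type (0.934) than with the array labelled sir4 null (0.919) or the ubp10 null (0.86). The part of the 5′ signal loss in the value for the array labelled sir4 null was not tested, so these values do not rank the strains by likeness.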
